A study of Gallus gallus with 6 samples.

How the data were processed

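Chromatin immunoprecipitation sequencing (ChIP-seq) for methylated lysine 4 of histone H3 (H3K4) was compared in 3 chicken cell populations. Embryonic stem cells (ESC) came from stage X blastoderms and were cultured for 24 h before purification. Primordial germ cells (PGC) came from genital ridges, after 4.5 d of incubation in the protocol text, while their stage label reads 72 h (stage 27). Spermatogonial stem cells (SSC) came from embryonic testes, at 18.5 d in the protocol text and 18 d in the stage label. Purification was by differential culture, with no sorting step described. The series title names dimethylated H3K4, but per the labels the antibody recognises both di- and trimethylated H3K4, so the signal is called H3K4 methylation here.

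Each population has 1 immunoprecipitated (IP) library and 1 input library, 6 in all. There are no replicates, so no p-value or standard error between conditions could be computed, and every comparison is between libraries, not conditions. Intervals and floors cover counting error only. Per the labels, the authors used CASAVA 1.8, FastQC, BWA and MACS2 with the genome build galGal4; versions of the last 3 tools, their settings and the step that counted reads per region are not stated.

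The authors deposited 3 tables of regions, 1 for each pair of populations. Per the file headers, each region has a read count in each of the 4 libraries of the pair. The deposited RPM values equal the count plus 1, divided by the library total in megareads (M), and the implied total is the same for every region. This gave totals of 26.03 M reads for ESC IP, 19.96 for ESC input, 20.24 for PGC IP, 24.98 for PGC input, 19.15 for SSC IP and 23.68 for SSC input, and 100% of the counts were recovered as whole numbers within 0.05 reads. The deposited fold enrichment is the ratio of IP RPM to input RPM in the same population. The deposited log2 fold change is the log2 of the ratio of the first population's enrichment to the second's, with no scaling for IP efficiency. The authors also marked in which population a region was a peak. Only regions with enrichment above 1 in both populations are listed (0 at or below 1), and no p or q is given. The planned count of regions past a p or q, with its stricter thresholds, could therefore not be made. Because of the limit on enrichment, a log2 ratio cannot exceed the log2 of the enrichment in the higher population. Regions without enrichment in 1 population are missing. Neither the base from which coordinates count nor any wider list of peaks is stated, and regions outside these tables are not analysed here.

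Enrichments and log2 ratios were recomputed from the RPM values of each library and differed from the deposited log2 values by at most 5.33e-15. A region that overlapped several genes was listed once per gene, so 90, 152 and 55 repeats were collapsed in ESC against PGC, ESC against SSC and PGC against SSC. A region counted as higher in a population when its enrichment ratio was at least 2-fold. A 95% counting interval for each log2 ratio came from the delta method on the 4 counts. Where the input of the population with the higher enrichment held 0 reads, the ratio was also computed with that input at a floor of 3 counts in place of the authors' added 1, and is given as a lower bound where the interval excluded no difference. Such a bound replaces the input of 0 reads alone and leaves out the counting error of the other reads, so the end of the interval nearest 0 is given beside it. Shares have exact Clopper-Pearson 95% intervals. A region was near a start when it lay within 1 kb of the closest transcription start in the authors' annotation.

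The median depth at listed regions ran from 11 to 23 reads per region in the IP libraries and from 4 to 6 in the inputs, and the median counting standard error of a log2 ratio was between 1.03 and 1.06. The procedure was tested on simulated Poisson counts with these depths, without any selection of called regions or limit on enrichment. Counting error alone put 27.8%, 25.8% and 27.9% of unchanged regions at 2-fold or more in the 3 comparisons. Of regions simulated with a 4-fold difference, 84%, 85% and 83% were found at 2-fold or more in the right direction. The interval covered the simulated value in 97.1%, 97.9% and 96.9% of regions.

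Genes were taken as the closest start in the authors' tables, and each gene had 1 value, from its region nearest the start, however far away that region lay. The 16 gene lists and the rule for named genes were chosen before the data were examined. The rule took the 8 genes with the largest ratio in each direction among called regions above the median signal, up to 2 members per list and direction beyond 2-fold, and 14 genes always. Each list with at least 3 listed members was described by the percentile of its median log2 ratio among 10000 random gene lists matched on deciles of mean IP signal. Such a percentile describes these libraries and is no test of the conditions. Random lists were not matched on the population of the call, which rests on the same signal as the ratio. In 300 random lists per comparison, 4.33%, 4.67% and 6.67% fell outside the central 95%. A reference table of gene names from another build matched 0 of 6437 gene IDs and 3440 of 3813 symbols (90.2%), and served only to update older symbols.

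Alternatives covered the fold threshold, centring of the log2 ratios, signal, peak height and width filters, the pseudocount, chromosomes, the region taken for a gene, the matching of random lists, the distance to starts and the overlap rule. Others were chosen after seeing the data: ratios of the IP libraries without inputs, regions with a read in both inputs, regions whose interval excluded no difference, matching on nearness to starts, and matching of Z and autosomal regions on the population of the call. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and overlaps used bedtools 2.31.1.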

Results

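H3K4 methylation, a histone mark of promoters and enhancers, was profiled in chicken embryonic stem cells (ESC), primordial germ cells (PGC) and spermatogonial stem cells (SSC). Each population had 1 IP and 1 input library, with totals from 19.15 M reads (SSC IP) to 26.03 M reads (ESC IP). The tables listed 4801 distinct regions for ESC against PGC, 5840 for ESC against SSC and 4823 for PGC against SSC, on the build galGal4. Listed regions held 0.642% and 0.832% of the ESC IP reads, 0.302% and 0.324% of the PGC IP reads, and 0.504% and 0.341% of the SSC IP reads, in the pair of tables that each population entered. These shares move with what was called, which covered 1379 kb and 1796 kb in ESC, 498.5 kb and 553 kb in PGC, and 993 kb and 737 kb in SSC.

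The regions called in the 3 populations lay at different distances from transcription starts. Of the ESC-called regions, 65.3% (95% interval 63.5 to 67.1) lay within 1 kb of a transcription start in the table against PGC and 66.0% (64.4 to 67.5) in the table against SSC. SSC-called regions lay there in 23.0% (21.4 to 24.7) and 18.5% (17.0 to 20.04) of cases, and PGC-called regions in 4.16% (3.34 to 5.12) and 3.40% (2.69 to 4.22). The median distance to the closest start was 541.5 bp and 523 bp for ESC-called regions, 3851 bp and 5740 bp for SSC-called regions, and 17353 bp and 18715 bp for PGC-called regions. ESC-called regions were wider, with medians of 363.5 bp and 367 bp against 223 bp and 222 bp for PGC and 249 bp and 237 bp for SSC. Their median enrichment over input was 6.13 and 5.98, compared with 2.96 in both tables for PGC and 3.71 in both for SSC. Few regions were called in PGC and in another population, 16 with ESC and 17 with SSC, while 397 were called in both ESC and SSC. The PGC widths lay near the smallest listed width of 200 bp. Regions called only in PGC held a median of 16 IP and 6 input reads in PGC. Calls at the level of noise cannot be told apart from real calls at distal sites in PGC, as given under other observations.

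**Figure D1:**
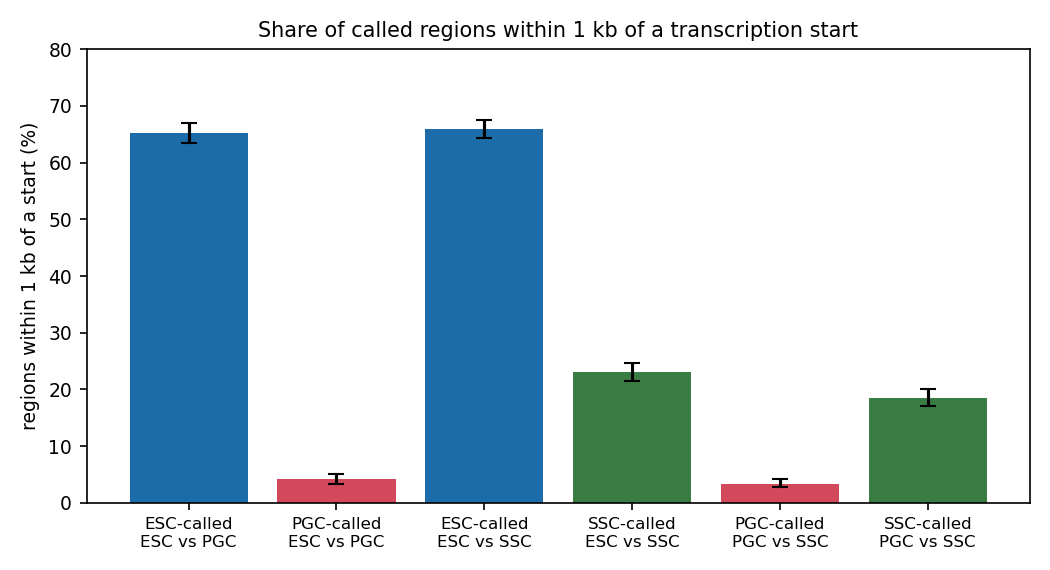
Share of called regions within 1 kb of a transcription start (%), for each population in each of its pair of tables; error bars are exact 95% binomial intervals. ESC-called regions sit at 65.3% and 66.0%, SSC-called at 23.0% and 18.5%, and PGC-called at 4.16% and 3.40%.

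ESC against PGC addressed how H3K4 methylation differs between the pluripotent starting population and early germ cells. Signal near starts of housekeeping genes and of regulators such as MYCN and TCF7L2 was higher in ESC, and of 2027 regions called only in PGC just 79 lay within 1 kb of a start. MYCN, a proto-oncogene transcription factor of stem and progenitor cells, had a log2 ratio of 2.74 (95% counting interval 2.08 to 3.41), and TFAP2C, a transcription factor of germ cell specification, had 3.46 (2.66 to 4.26). The Wnt pathway transcription factor TCF7L2 had 4.66 (2.78 to 6.55) and the protocadherin PCDH1 had 4.75 (2.84 to 6.66). Of the 4801 regions, each listed because it was called in at least 1 of the populations, 2325 (48.4%) were at least 2-fold higher in ESC and 1126 (23.5%) in PGC. As listed regions had enrichment above 1 in both populations, each ratio was capped by the region's own enrichment. The median enrichment was 6.13 in ESC for regions called only there and 3.00 in PGC for regions called only there. The counts in each direction therefore depend partly on this limit.

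At single genes, the ESC-called region of MYCN (chromosome 3, 98777270 to 98780595, 5' UTR) held 519 IP and 43 input reads in ESC and 67 and 61 in PGC. The TFAP2C region (chromosome 20, 12288721 to 12292154, first intron) held 490 and 22 in ESC and 63 and 52 in PGC. The region of TCF7L2 (chromosome 6, 26590173 to 26590844) held 104 and 2 against 17 and 20, and that of PCDH1 (chromosome 13, 1408033 to 1409479) held 172 and 2 against 19 and 14. EIF2A, RARS, the capping enzyme gene RNGTT, the diacylglycerol kinase gene DGKH, the glutamine transporter gene SLC38A1 and the microRNA gga-mir-6687 had no read in the ESC input. With that input at 3 counts, enrichment in ESC was at least 9.11-fold higher for EIF2A, 8.49-fold for RARS, 8.28-fold for RNGTT, 7.25-fold for DGKH, 7.87-fold for SLC38A1 and 9.32-fold for gga-mir-6687, before counting error in the other reads. The counting intervals of the log2 ratios began at 1.10, 1.51, 1.14, 1.20, 0.88 and 0.78 in the same order. In the other direction, KIAA0922 had -2.82 (-5.10 to -0.55), the sorting receptor gene SORCS2 -2.23 (-4.09 to -0.36), UBE2E3, a ubiquitin-conjugating enzyme, -2.17 (-4.08 to -0.26), and the opioid receptor gene OPRK1 -2.15 (-3.95 to -0.34). DAGLB had -2.15 (-3.84 to -0.45), the Tudor domain gene TDRD15 -2.11 (-4.05 to -0.17) and gga-mir-1799 -2.21 (-3.90 to -0.52). At its region nearest the start, 66693 bp away, TDRD15 had -0.95 (-3.39 to 1.49). For gga-mir-1632, whose PGC input held 0 reads, the direction was not detectable at this depth (-3.05, -6.37 to 0.27). These PGC-called regions lay from 6150 bp (KIAA0922) to 224589 bp (gga-mir-1632) away from the closest start.

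By list, the median over all genes with a symbol was 1.15, so a list with a lower median ran below the general difference in favour of ESC. Housekeeping genes had a median of 2.86 (2.47 with inputs of 0 at the floor), all 6 at least 2-fold higher in ESC, among them RPL19 at 3.69 (1.43 to 5.94) and RPS6 at 2.81. All 6 listed early lineage regulators were at least 2-fold higher in ESC, with a median of 1.53. GATA5, an endoderm and heart regulator, had 2.73 (1.58 to 3.89) and EOMES, a mesendoderm regulator, 2.25 (0.30 to 4.20). All 6 members of either list, housekeeping or early lineage, were called in ESC and 0 in PGC. Of 3 pluripotency genes (median 2.74), KLF5 at 3.29 (1.83 to 4.76) and MYCN were higher in ESC and TFCP2L1 had -0.96. Of 12 FGF and MAPK genes (median 1.66, or 1.32 with inputs of 0 at the floor), 7 were higher in ESC and 2 in PGC: the receptor FGFR4 had 2.75 (1.26 to 4.24) and the growth factor homologue FGF13 had -1.01 (-3.21 to 1.20). Of 6 H3K4 methylation enzymes and partners (median 1.73), 5 were higher in ESC, with SETD7 at 3.14 (0.46 to 5.81) and WDR5 at 1.95 (-0.09 to 3.98), while the demethylase KDM1B had -1.42 (-3.95 to 1.11).

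Of 10 TGF-beta and BMP genes (median 1.10), 5 were higher in ESC and 2 in PGC, such as BMPR2 at 2.83 (0.95 to 4.72), SMAD6 at 2.30 (0.94 to 3.65) and BMP4 at -1.70 (-3.33 to -0.08). Of 6 Notch genes (median 0.57), 3 were higher in ESC and 1 in PGC, with the ligand DLL1 at 2.11 (0.90 to 3.33) and RBPJ at -1.86 (-3.97 to 0.26). Of 4 Wnt genes (median 0.61), TCF7L2 and WNT5B at 1.90 (-0.62 to 4.41) were higher in ESC and WNT11 at -2.01 (-4.31 to 0.30) in PGC. The regions of BMP4, RBPJ and WNT11 lay 33341, 73831 and 116711 bp from the closest start. Those of TFCP2L1 and FGF13 lay 87242 and 64127 bp away. By contrast, the regions of TCF7L2 and SMAD6 lay 22 and 460 bp away, so members of a list stand for unlike places. With the median of all genes subtracted, these lists changed sign, to -0.05 for TGF-beta and BMP, -0.58 for Notch and -0.54 for Wnt. The 3 listed somatic gonad genes, GATA4, FSHR and NR2F2, had a median of -1.17, and 4 fibroblast and mesenchymal genes had -0.68, with COL1A2 at -1.92 (-4.18 to 0.35) and FBN1 at 1.46 (-0.37 to 3.29). The other lists had fewer than 3 members: 2 primordial germ cell and piRNA genes (median 1.25), 2 blood and endothelial genes (0.06), the spermatogonial gene ITGB1 at 1.60 (-1.04 to 4.24), the retinoic acid gene CRABP1 at -0.07, and no meiosis or HOX gene. None of the 10 lists with at least 3 members lay outside the central 95% of matched random lists; the nearest, housekeeping, stood at percentile 97.3 of 10000 random lists, and at 97.9 with random lists also matched on nearness to starts.

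After centring on the median log2 ratio (0.90), which shifts every region alike, 1374 regions were higher in ESC and 1888 in PGC. Among regions at least 2-fold apart, the counting interval excluded no difference for 1138 higher in ESC and 101 higher in PGC. In simulation it did so for 2.83% of unchanged regions, both directions together. Counting error alone could therefore give a large part of the 101 among 4801 regions. The genes named in favour of PGC were picked as the largest ratios. Without inputs the log2 ratio was 2.18 for TCF7L2, 2.75 for PCDH1, 1.82 for RARS and 1.959 for DGKH, between -1.50 and -1.05 for KIAA0922, SORCS2, UBE2E3, OPRK1 and TDRD15, and under 2-fold for gga-mir-1799 (-0.89), DAGLB (-0.82) and gga-mir-1632 (-0.73).

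**Figure D2:**
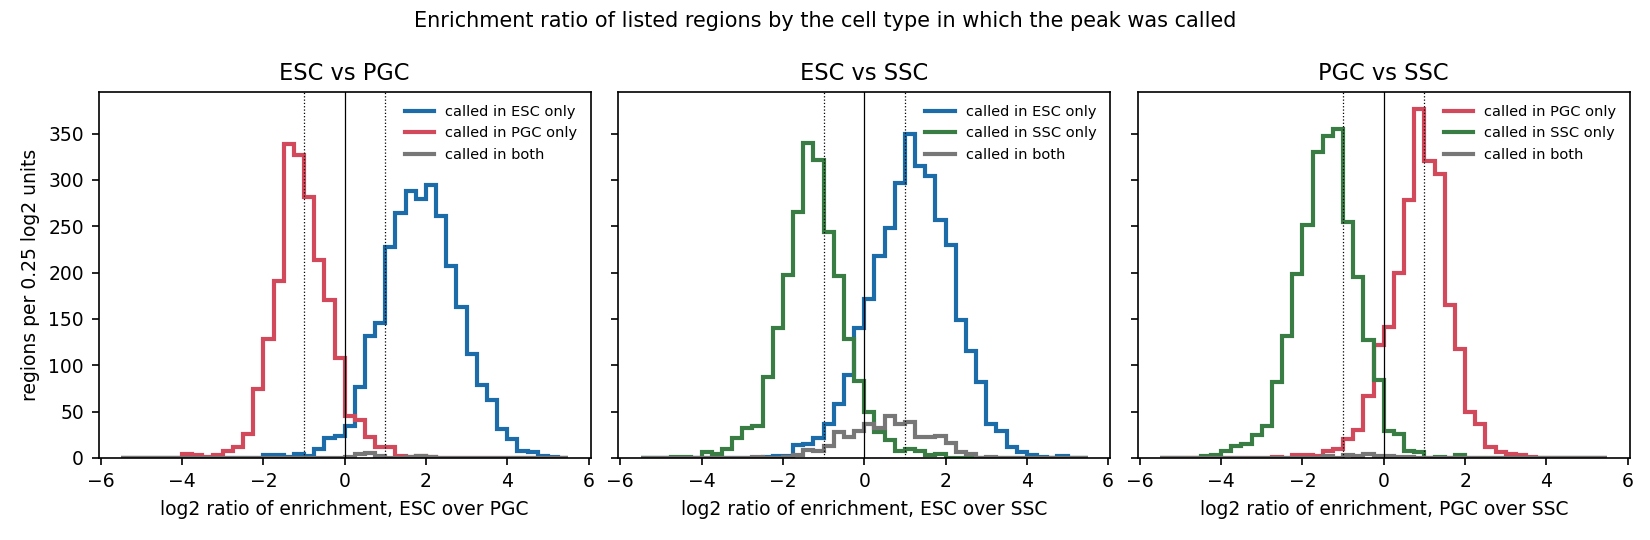
Number of regions per bin of log2 enrichment ratio, 1 panel per comparison, with lines by the population in which the peak was called; dotted lines mark 2-fold. Median log2 ratios were 1.88 for regions called only in ESC and -1.07 for only PGC, 1.20 for only ESC and -1.27 for only SSC, and 0.93 for only PGC and -1.37 for only SSC; centring on each comparison's median (0.90, 0.31 and -0.42) shifts every line by that amount.

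ESC against SSC set the pluripotent population against germline stem cells of the late embryonic testis. Genes of the somatic gonad carried more signal in SSC: 7 of 8 listed members were at least 2-fold higher, with a median log2 ratio of -1.71. They included NR5A1, a regulator of steroid-producing cells, at -2.44 (-4.63 to -0.26), LHX9, a regulator of gonad formation, at -2.33 (-3.91 to -0.74), and the inhibin subunit gene INHBB at -1.83 (-3.04 to -0.63). Early lineage regulators were higher in ESC in 5 of 6 cases, with the homeobox gene MSX1 at 2.61 (1.72 to 3.49), as was the ribosomal protein gene RPL19 at 3.25 (0.96 to 5.54). Of the 5840 regions, 2051 (35.1%) were at least 2-fold higher in ESC and 1534 (26.3%) in SSC.

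The somatic gonad list stood at percentile 0 of the 10000 matched random lists, and at the region nearest the start all 8 members were called in SSC and 0 in ESC. Such a call by itself favours a ratio below 0 and a low percentile. All regions called only in SSC had a median of -1.27, while the random lists, not matched on the call, had a median of 0.78. The interval and the values of single members are therefore given beside the percentile. The interval excluded no difference for 4 of them, INHBB, LHX9, NR5A1 and NR2F2, a nuclear receptor of interstitial and mesenchymal cells, at -1.58 in the region nearest its start. WT1 had -1.94, TCF21 -1.34, GATA4 -1.0004 and EMX2 -0.83, with intervals that included 0. Farther along the gene, an NR2F2 region (chromosome 10, 15330032 to 15331985) held 161 IP and 21 input reads in SSC and 65 and 34 in ESC, a log2 ratio of -2.65 (-3.53 to -1.78). Beside this list, fibroblast and mesenchymal genes had a median of -1.22 over 6 genes at percentile 3.0. The percentile was 0.92 with the mean over each gene's regions and 8.01 with random lists also matched on nearness to starts. Of the 6 genes, 4 were at least 2-fold higher in SSC. Among them the proteoglycan gene LUM had -3.08 (-5.71 to -0.45) and the collagen gene COL5A1 -1.75 (-3.82 to 0.31). In the other direction, FBN1, called in ESC, had 0.73 (-1.30 to 2.75).

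**Figure D3:**
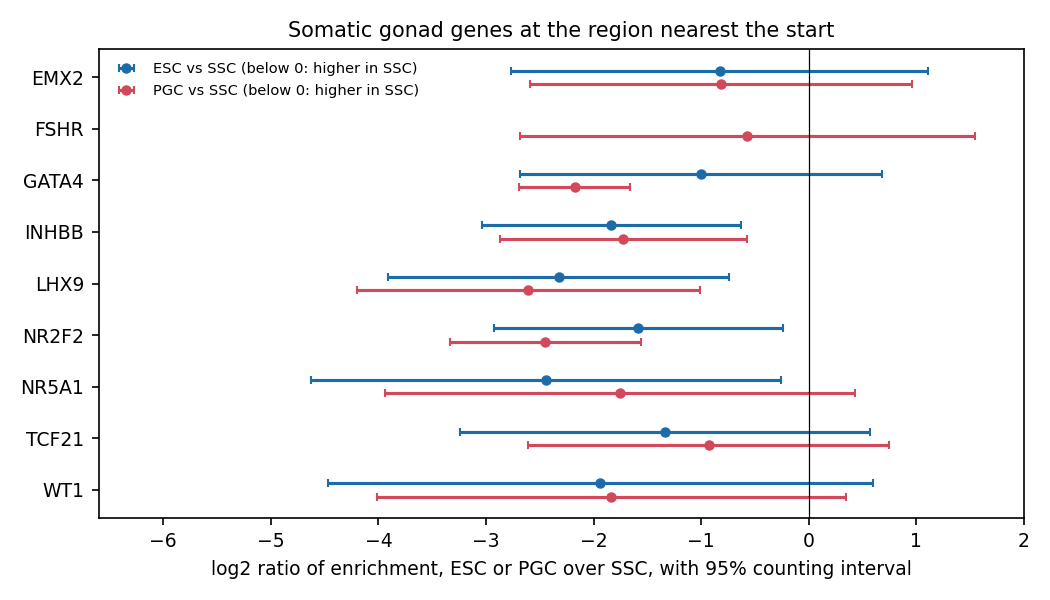
Log2 ratio of enrichment for each somatic gonad gene at its region nearest the start, ESC over SSC and PGC over SSC, with 95% counting intervals; values below 0 are higher in SSC. All 8 genes listed in ESC against SSC and all 9 in PGC against SSC lie below 0, from -2.61 (LHX9) to -0.57 (FSHR, both in PGC against SSC).

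Among the largest ratios, PCDH1 had 4.97 (3.02 to 6.91), the proteasome gene PSMB2 4.04 (2.05 to 6.03), the small nucleolar RNA SNORA73 3.70 (2.62 to 4.77) and VPS39 3.59 (1.24 to 5.94). With an ESC input of 0 reads set to 3 counts, enrichment in ESC was at least 9.09-fold higher for EIF2A, 6.98-fold for the zinc transporter gene SLC39A11, 5.79-fold for the histone acetyltransferase gene HAT1 and 4.34-fold for C16orf62, before counting error in the other reads. The intervals of their log2 ratios began at 0.75, 1.20, 1.02 and 0.55. Higher in SSC were the Wnt receptor gene FZD1 at -3.62 (-6.11 to -1.13), PCDH18 at -3.08 (-5.08 to -1.09), the follistatin-like gene FSTL1 at -2.76 (-4.79 to -0.73) and C21orf91 at -2.75 (-5.09 to -0.41). At its region nearest the start, 1147 bp away, FZD1 had -2.43 (-5.08 to 0.23). PSMD7 had -2.71 (-4.54 to -0.88), the semaphorin co-receptor gene NRP1 -2.63 (-4.87 to -0.39) and LGALSL -2.56 (-4.61 to -0.52).

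Early lineage regulators had a median of 1.88 over 6 genes (percentile 99.2), 5 of them at least 2-fold higher in ESC, including TFAP2A at 2.18 (-1.14 to 5.505) and GATA5 at 2.60 (-0.40 to 5.59). The interval excluded no difference for 1 of the 6, MSX1. All 6 were called in ESC and 0 in SSC, which by itself favours a ratio above 0. The 3 primordial germ cell and piRNA genes had a median of 2.38 (percentile 98.6): TFAP2C had 3.20 (2.25 to 4.15), the piRNA pathway gene TDRD7, with 0 reads in the ESC input, had 2.38 (-1.36 to 6.12), and the chemokine receptor gene CXCR4 had -1.40 (-3.39 to 0.60). That median was 0.80 with the TDRD7 input at the floor, and its percentile was 65.2 with the mean over each gene's regions and 91.4 without inputs. Notch genes had -1.59 over 6 genes (percentile 0.61), 4 higher in SSC, such as MAML1 at -2.97 (-5.61 to -0.34) and JAG1 at -1.81 (-4.24 to 0.63), and 1 higher in ESC, DLL1 at 1.55 (0.35 to 2.75); the interval excluded no difference for 1 of the genes in each direction. The Notch percentile was 2.62 with random lists also matched on nearness to starts, 4.795 with the largest ratio of each gene and 10.7 with the mean over each gene's regions. These 4 of 12 lists lay outside the central 95%.

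The remaining lists lay within it, against a median of 0.57 over all genes. Of 10 housekeeping genes (median 1.27, or 0.79 with inputs of 0 at the floor), 6 were higher in ESC and 2 in SSC, HPRT1 at -3.11 (-5.81 to -0.41) and RPL5 at -1.13 (-2.83 to 0.57). The 6 H3K4 methylation enzymes and partners had a median of 1.26, with the demethylase KDM5A at 2.04 (0.997 to 3.08) and SETD7 at 2.55 (-0.04 to 5.14). The 5 pluripotency genes had -0.30, with KLF5 at 2.17 (0.67 to 3.67), MYCN at 1.71 (1.05 to 2.38), KLF2 at -1.14 (-3.70 to 1.43) and LIN28B, an RNA-binding regulator, at -0.30 (-2.96 to 2.37). The 3 meiosis genes had -1.51, with SYCP3, of the synaptonemal complex, at -2.08 (-4.20 to 0.03) and the recombinase DMC1 at -1.51 (-3.61 to 0.58). Of 6 Wnt genes (median -0.91), TCF7L2 had 3.23 (1.33 to 5.14), WNT5B 1.90 (-0.46 to 4.25), FZD1 -2.43 (-5.08 to 0.23) and WNT9A -1.10 (-2.97 to 0.76). The WNT9A region lay 139717 bp from the closest start.

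The 10 TGF-beta and BMP genes, INHBB among them, had -0.30, with LEFTY2 at 1.12 (-0.97 to 3.21) and BMP5 at -1.05 (-3.09 to 0.98). The 11 FGF and MAPK genes had 0.48, or -0.09 after centring on all genes, with FGFR4 at 2.61 (1.10 to 4.12), FGFR2, with 0 reads in the ESC input, at 3.22 (-0.32 to 6.76) and SPRED2 at -2.11 (-4.41 to 0.19). Fewer than 3 members were listed for spermatogonial genes (2, median -0.45, or 0.34 with the input of 0 at the floor), blood and endothelial genes (2, 0.75, with GATA2 at 1.65), HOX genes (HOXB9 at -1.56, -4.44 to 1.31) and retinoic acid genes (0). For the spermatogonial surface gene ITGB1, whose SSC input held 0 reads, the direction was not detectable at this depth (-1.16, -4.50 to 2.19).

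After centring on the median log2 ratio (0.31), which shifts every region alike, 1572 were higher in ESC and 1904 in SSC, with a pseudocount of 5 the counts were 1320 and 1370, and without inputs 2390 and 1009. Without inputs, the log2 ratios of PCDH18, FSTL1, C21orf91, PSMD7 and LGALSL lay between -0.65 and -0.34 and that of HAT1 was 0.78, and by the counting interval 699 and 282 regions were higher in ESC and SSC. At regions called only in SSC, the median input was 4 reads in SSC (total 23.68 M) and 5 in ESC (19.96 M). Ratios in favour of SSC thus rest partly on low SSC input.

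**Figure D4:**
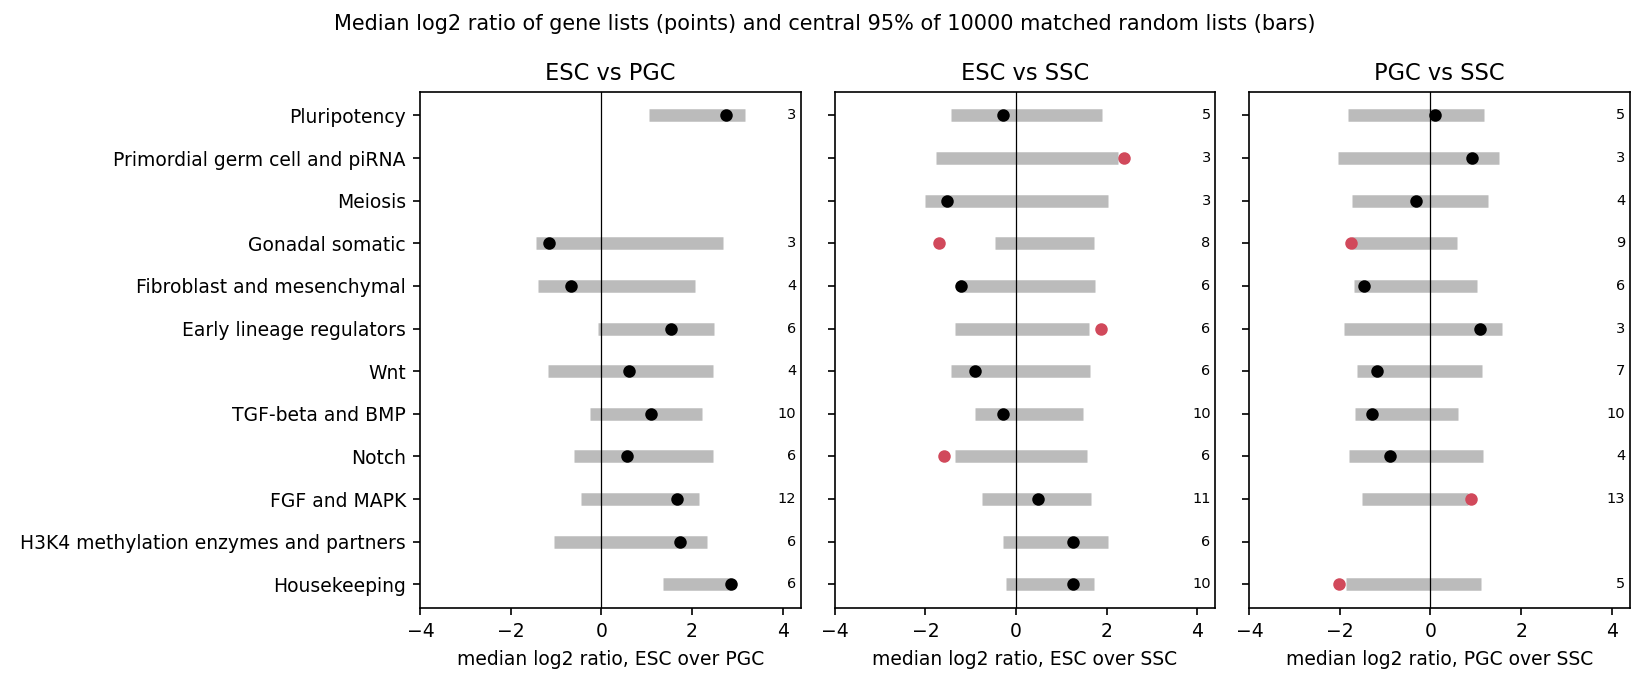
Median log2 ratio of each gene list with at least 3 listed members (points; red outside the bar) and the central 95% of 10000 random lists matched on signal (grey bars), 1 panel per comparison; the number at the right is the count of members. Centring on all genes (1.15, 0.57 and -0.49) turns the sign of Wnt, Notch and TGF-beta and BMP in ESC against PGC, of FGF and MAPK in ESC against SSC, and of meiosis in PGC against SSC.

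PGC against SSC compared earlier and later germline populations. Signal was higher in SSC at somatic gonad and housekeeping genes, while the FGF and MAPK list had a median of 0.90 that reversed with other regions of each gene. The BMP receptor gene BMPR2 had a log2 ratio of -2.33 (-3.37 to -1.29), NR2F2 -2.45 (-3.34 to -1.56), LHX9 -2.61 (-4.20 to -1.01) and FZD1 -3.70 (-6.07 to -1.33). Of the 4823 regions, 1023 (21.2%) were at least 2-fold higher in PGC and 1822 (37.8%) in SSC.

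Somatic gonad genes had a median of -1.76 over 9 genes (percentile 2.29), 6 of them at least 2-fold higher in SSC, and the interval excluded no difference for GATA4, a regulator of gonadal and cardiac development, at -2.17, INHBB at -1.72, LHX9 and NR2F2. The 6 fibroblast and mesenchymal genes had -1.46 (percentile 8.28), 4 of them higher in SSC, including COL6A3 at -2.06 (-4.12 to -0.01) and COL5A1 at -1.94 (-3.65 to -0.23). All 5 housekeeping genes were higher in SSC, with a median of -2.03 (percentile 0.965), such as RPS3 at -2.13 (-4.44 to 0.17), HPRT1 at -2.39 (-4.94 to 0.15) and ACTB at -1.73 (-3.42 to -0.05), and the interval excluded no difference for 2 of the 5. All 5 were called in SSC and 0 in PGC, which by itself favours a ratio below 0. Of the 9 somatic gonad genes, 8 were called in SSC and 1 in PGC, which also favours a ratio below 0. The 13 FGF and MAPK genes had 0.90 (percentile 98.6), 5 higher in PGC and 2 in SSC, with SPRED2 at 1.58 (-0.73 to 3.89) and DUSP6 at -1.52 (-3.81 to 0.77); the interval included 0 for all 13. These 3 of 11 lists lay outside the central 95%. With the mean over each gene's regions the percentiles were 6.46 for somatic gonad genes and 80.3 for FGF and MAPK, with random lists matched on width that of somatic gonad genes was 3.065, and with regions within 5 kb of the start alone the percentiles were 8.76 for somatic gonad and 3.45 for housekeeping genes. The FGF and MAPK median was -0.59 with the largest ratio of each gene and -0.21 within 5 kb, and its percentile was 94.5 without inputs.

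Among the largest ratios in favour of PGC, the intestinal homeobox gene ISX had 3.26 (0.71 to 5.81), THADA 3.25 (0.71 to 5.78) and B3GAT1 2.79 (0.61 to 4.97). ARHGAP12 had 2.53 (0.53 to 4.54), KIAA0922 2.46 (0.14 to 4.77) and CAVIN2 2.34 (0.26 to 4.42), and ARHGAP15, with 0 reads in the PGC input, was at least 4.45-fold higher in PGC with that input at 3 counts (interval of the log2 ratio from 0.54). Higher in SSC were the splicing factor gene PRPF8 at -3.59 (-6.29 to -0.88), CUL5 at -3.47 (-6.10 to -0.85), EGLN3, an oxygen-sensing hydroxylase, at -3.44 (-6.00 to -0.88) and the stress-response factor ATF4 at -3.38 (-6.08 to -0.69). With SSC inputs of 0 reads at 3 counts, enrichment in SSC was at least 7.42-fold higher for BBX, 6.34-fold for SUSD1 and 3.89-fold for TTLL12, before counting error in the other reads. The ends of their intervals nearest 0 were -1.30, -0.92 and -0.35. The FZD1 region (chromosome 2, 22263553 to 22263855) held 23 IP and 1 input reads in SSC and 11 and 12 in PGC.

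The other lists lay within the central 95%, against a median of -0.49 over all genes. Of 10 TGF-beta and BMP genes (median -1.29), 6 were higher in SSC, such as SMAD6 at -1.88 (-3.68 to -0.08), and 2 in PGC, SMAD5 at 1.58 (-0.53 to 3.69) and BMPR1B at 1.10 (-0.89 to 3.09). Of 7 Wnt genes (median -1.17), 4 were higher in SSC, including SFRP2 at -1.59 (-3.42 to 0.25), and TCF7 had 1.05 (-0.90 to 3.00). The 4 Notch genes had -0.90, with JAG2 at -1.64 (-3.39 to 0.11), NOTCH2 at -1.42 (-3.14 to 0.30) and RBPJ at 1.08 (-1.25 to 3.42). The RBPJ region here lay 1783 bp from the start and is not the region given in ESC against PGC. The 5 pluripotency genes had 0.09, with KLF5 at 1.4999 (-0.45 to 3.45), TFCP2L1 at 1.20 (-0.51 to 2.91) and KLF2 at -2.32 (-4.67 to 0.02). The 3 early lineage regulators, TFAP2A, EOMES and MSX1, had 1.08, and the 3 primordial germ cell and piRNA genes 0.91, with TDRD15 at 1.48 (-1.0007 to 3.97) and CXCR4 at -1.61 (-3.50 to 0.27). The 4 meiosis genes had -0.33, or 0.16 after centring on all genes, with TEX11 at -2.23 (-4.53 to 0.08) and DMC1 at -1.24 (-3.05 to 0.57). Fewer than 3 members were listed for HOX genes (HOXB9 at -2.46, -5.06 to 0.13, and HOXB1 at -1.62, -3.55 to 0.32), blood and endothelial genes (2, median 0.22), spermatogonial genes (DMRT1, a testis-determining gene of the Z chromosome, at 0.05, -2.15 to 2.25), H3K4 methylation genes (KDM5A at -0.97) and retinoic acid genes (0).

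After centring on the median log2 ratio (-0.42), which shifts every region alike, 1599 were higher in PGC and 1225 in SSC, and without inputs 1194 and 1016. At regions called only in SSC, the median input was 4 reads in SSC (total 23.68 M) and 7 in PGC (24.98 M). Here too, ratios in favour of SSC rest partly on low SSC input. With a pseudocount of 5 the counts were 500 and 1198, and by the counting interval 87 and 462. In simulation the interval excluded no difference for 3.09% of unchanged regions, both directions together. Counting error alone could therefore give a count near the 87 among 4823 regions. The genes named in favour of PGC were picked as the largest ratios. Without inputs the log2 ratio was -1.23 for BBX and -1.08 for FZD1, and under 2-fold for ARHGAP15 (0.85), B3GAT1 (0.84), ARHGAP12 (0.998) and TTLL12 (-0.62).

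Of the 14 genes chosen in advance as markers of pluripotency and germ cells, 3 had a listed region in any table, ITGB1, LIN28B and DMRT1. No region was listed for NANOG, POU5F3, SOX2, DDX4, DAZL, PIWIL1, KIT, GFRA1, ZBTB16, ITGA6 or STRA8, which in tables limited to called regions with enrichment above 1 in both populations says nothing of the level of the mark there.

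The 3 tables shared many regions. At least 1 base was shared with a region of another table for 75.7% of regions in ESC against PGC, 67.2% in ESC against SSC and 56.4% in PGC against SSC. ESC-called regions overlapped the population's other table most often: 92.3% of those in the table against PGC overlapped the table against SSC, and 70.8% in reverse. For SSC-called regions these shares were 61.2% and 64.6%, and for PGC-called regions 53.1% and 47.2%. Both tables of a population hold the same libraries, so these shares do not measure how reproducible the calls are. At 260 regions found in all 3 tables, the sum of the log2 ratios of ESC over PGC and PGC over SSC differed from that of ESC over SSC by a median of -0.003877 (SD 0.867 across regions), with a Spearman correlation of 0.653 across regions, which are not independent replicates. The same libraries enter both sides, so this is an arithmetic check on regions with different bounds.

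On the Z chromosome, the median log2 ratio minus that of autosomal regions was 0.75 in ESC against PGC (133 regions on Z, percentile 99.98 of random sets of as many regions), -0.35 in ESC against SSC (283 regions, percentile 1.9) and -0.78 in PGC against SSC (220 regions, percentile 0). Regions on Z were called in ESC alone in 97 cases and in PGC alone in 36 in the first table. They were called in ESC alone in 124 cases and in SSC alone in 140 in the next, and in PGC alone in 46 and in SSC alone in 174 in the last. Relative to autosomal regions of the same call, which rests on the same signal as the ratio, the differences were 0.0723, 0.0544 and 0.0566. Among random sets matched on call, the reported differences stood at percentiles 92.3, 96.8 and 73.0. SSC came from testes of male (ZZ) embryos, while the sex of the ESC and PGC pools is not given by the labels. The differences and call numbers on Z therefore cannot be told apart from a difference in sex. Regions on Z near named genes included TDRD7, SUSD1 and DMRT1.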

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

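No paired analysis was possible because each population had 1 IP and 1 input library, with no shared animal or batch named. The alternatives without inputs, with the counting interval, with a read in both inputs and with matching on nearness to starts or on the population of the call were chosen after the data were seen; the others were planned. The planned thresholds on an adjusted p could not be run, since no p is listed. Of the alternative counts of regions higher in 1 population, 43 stayed within 1.5 times the reported count and 29 moved; the cause was not tested except where fewer regions or a stricter threshold lower a count by construction. At 4-fold, 1247 regions were higher in ESC and 130 in PGC, 693 in ESC and 340 in SSC, and 111 in PGC and 515 in SSC; at 1.5-fold, 1596 were higher in PGC than in SSC. By the counting interval these pairs of counts were 1138 and 101, 699 and 282, and 87 and 462. In simulation 2.83%, 2.15% and 3.09% of unchanged regions passed it, both directions together. The limit of enrichment above 1 in both populations caps every ratio, and so also shapes the counts by threshold and by interval. Centring on the median moved ESC against PGC to 1374 and 1888 and the regions higher in PGC than in SSC to 1599, but centring shifts every region alike and balances the directions by construction. Among regions above the median signal, 288 were higher in PGC than in ESC, 358 in SSC than in ESC, 422 in PGC than in SSC and 1020 in SSC than in PGC. Above the lower quartile of peak height, 629 were higher in PGC than in ESC and 875 in SSC than in ESC, and without regions under the lower quartile of width, 663 and 907. With a pseudocount of 5, 1320 were higher in ESC than in SSC, 500 in PGC than in SSC and 1198 in SSC than in PGC. Without inputs, 1009 were higher in SSC than in ESC and 1016 in SSC than in PGC. The share of ESC-called regions near starts rose to 75.6% within 2 kb and 82.8% within 5 kb in the table against PGC, and to 76.2% and 83.3% in that against SSC. For PGC-called regions it was 9.35% and 24.0% against ESC and 9.19% and 22.2% against SSC, and for SSC-called regions 37.7% and 53.97% against ESC and 32.4% and 47.4% against PGC, so the order ESC, SSC, PGC held at 1 kb, 2 kb and 5 kb, and wider windows raise each share by construction. In ESC against PGC, 1 list (housekeeping) in place of 0 lay outside the central 95% with the mean over a gene's regions, with random lists matched on width or on nearness to starts, and without inputs. In PGC against SSC, 2 lists in place of 3 did with random lists matched on width (somatic gonad genes at percentile 3.065), 1 with the mean over a gene's regions and 0 with regions within 5 kb of the start; in ESC against SSC the number ran from 3 to 5 around the reported 4. Within 5 kb, 7 of 10, 9 of 12 and 7 of 11 lists still had 3 members. The FGF and MAPK list of PGC against SSC reversed to -0.59 with the largest ratio of each gene and to -0.21 within 5 kb, ITGB1 in ESC against SSC reversed to 1.09 without inputs, and the cause was not tested. The Z chromosome differences of 0.75, -0.35 and -0.78 moved to 0.0723, 0.0544 and 0.0566 relative to autosomal regions of the same call, but a call rests on the same signal as the ratio, so this matching can also remove a real difference. The share of PGC against SSC regions found in another table fell from 56.4% to 52.5% when 0.5 of both regions had to be shared, and the other overlaps, the sum of steps and the Z chromosome differences against long autosomes kept their values within their spread. Depth limited single regions: of simulated regions with a 2-fold difference, 50%, 54% and 46% were found at 2-fold or more, so an unlisted gene or a ratio near 2-fold says little about a single gene.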

Other observations

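The tests of IP efficiency, noise-level calls, input reads, somatic cells and developmental regulators, and the matching of annotation groups on nearness to starts, were chosen after the result was seen; that of sequencing depth was chosen before. Gene ontology groups in the authors' annotation with 15 to 300 listed genes numbered 173, 204 and 145 in the 3 comparisons. With random groups matched on signal alone, as for the gene lists, 36, 28 and 14 lay outside the central 95%. Matched also on nearness to starts, 11, 17 and 10 did, where chance would give 8.65, 10.2 and 7.25 on average. The groups share genes, so a single group's percentile, picked out afterwards, carries little weight. The 45 genes of the ribosome group had a median log2 ratio of 2.64 in ESC against PGC (percentile 99.6 of random groups matched on signal and nearness to starts), 43 of them at least 2-fold higher in ESC. In ESC against SSC the group's 59 genes had 1.69 (percentile 99.7), and in PGC against SSC its 21 genes had -1.53, 15 of them higher in SSC, at percentile 6.895, within the central 95%. Extracellular region genes (46, median -0.90, percentile 0.295) and cell adhesion genes (45, median -1.01, percentile 1.83) had more signal in SSC than in ESC, or -0.54 and -0.95 with inputs of 0 at the floor. Extracellular matrix genes (24, median -1.17, percentile 1.30) had more in SSC than in PGC. Ion transport genes had medians of -0.97 in ESC against PGC (44 genes, percentile 1.74) and 0.73 in PGC against SSC (61 genes, percentile 99.8), and 18.2% and 3.28% of these regions lay within 1 kb of a start.

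Some genes gathered many called regions, and these were chosen after their values were seen. NR2F2 had 12 SSC-called regions in the table with ESC (median log2 ratio -1.37) and 9 in the table with PGC, GATA4 had 7 and 5, BMPR2 9 and 5, and EBF1, a regulator of B cell and mesenchymal fates, 5 and 6. C21orf91 had 9 against ESC, and the endothelin receptor gene EDNRA and the repressor gene BCL6 5 each. In the table with PGC, 10 genes with a symbol had at least 5 SSC-called regions, among them GATM with 6, and NRP1 (median -2.27), PCDH18 (median -2.58), ANKRD50, CHD2 and QKI with 5 each. ESC-called regions numbered 5 at TFAP2A, HDAC2 and EPC1 against PGC and 5 at EOMES, FUBP1, HDAC2 and EPC1 against SSC. No gene with a symbol had 5 or more PGC-called regions.

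Signal at ESC-called regions near starts was higher in ESC than in PGC, with a median log2 ratio of 1.98. A call rests on the same signal as the ratio, so the call itself favours this direction. Regions called only in PGC had a median of -1.07. Whether sequencing depth of the ESC IP library shaped which regions were called stays open, as peaks were not called again. With every library thinned to 19.96 M reads, the median at these fixed regions was 2.01 (1.99 to 2.05 over 100 draws). A ratio scaled by library totals at fixed regions is not expected to move with depth. Lower IP efficiency in the PGC library cannot be told apart from other differences: ribosome and translation genes near starts had a median of 2.53 (95% bootstrap interval 2.30 to 2.82), but all 62 were called in ESC and 0 in PGC. As random sets of as many genes near starts had medians from 1.40 to 2.36, a value against it could hardly occur. A lower level of the mark over the whole genome in PGC would give the same values and stays open, untested, as does any difference between the populations.

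PGC-called regions lay away from starts and were seldom called in ESC or SSC. A shortage of PGC input reads, which would raise enrichment there, was argued against: PGC input RPM over ESC input RPM at these regions had a median log2 of 0.091. Calls at the level of noise cannot be told apart from real calls at distal sites: 30 of 3255 PGC-called regions overlapped regions called in ESC or SSC, 1.59 times the 18.9 of regions shifted along their chromosomes, above the upper end (28) of the central 95% of shifts but under the ratio of 2 set for real overlap. By the same measure, 397 SSC-called regions overlapped ESC-called ones, 20.9 times the 18.97 of shifted regions. A distinct set of PGC regions stays open, untested.

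Somatic gonad genes carried more signal in SSC than in ESC. All 8 were called in SSC and 0 in ESC, which by itself favours this direction. Higher IP efficiency in the SSC library cannot be told apart from other differences. Ribosome and translation genes near starts had a median log2 ratio of 1.49 (1.23 to 1.77, 81 genes), higher in ESC. But 79 of them were called in ESC and 21 in SSC, so a median below 0 could hardly occur. The 21 called in SSC were also higher in ESC (1.02 to 1.801), but most of them were called in ESC too. More signal in SSC at developmental regulators of every kind stays open as well. Early lineage regulators had 1.88 (0.849 to 2.60, 6 genes), but all 6 were called in ESC and 0 in SSC. Somatic testis cells in the SSC culture may contribute, since only differential culture and no sort is described, but this cannot be told apart from the mark in SSC themselves: the fibroblast and mesenchymal list, with LUM at -3.08 and COL5A1 at -1.75, stood at percentile 8.01 when matched on signal and nearness to starts, between the bounds of 2.5 and 50 set for either answer. INHBB also stands in the TGF-beta and BMP list and PDGFRA in the FGF and MAPK list, and how many of these genes SSC express was not measured here. A shortage of SSC input reads, which would raise enrichment in SSC, was not tested for these genes.

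Input reads per kb on Z relative to autosomes, at regions called in the other population, were 0.735 for PGC (95% bootstrap interval 0.643 to 0.823) and 1.17 for SSC (1.04 to 1.30) at ESC-called regions, and 0.673 for PGC (0.613 to 0.732) and 0.783 for ESC (0.718 to 0.856) at SSC-called regions. At PGC-called regions they were 0.823 for ESC (0.697 to 0.953) and 1.09 for SSC (0.944 to 1.25). As the sex of the ESC and PGC pools is not given, what these densities owe to the number of Z copies was not tested.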
